A study of Mus musculus with 3 samples.

How the data were processed

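Cells were sorted by flow cytometry, per the labels' protocols. Thymic stromal cells were taken as CD45-negative and EpCAM-positive, and split into cTEC, positive for Ly51 and negative for the lectin UEA1, and mTEC, negative for Ly51 and positive for UEA1. Epidermal cells of the trunk and back were taken as EpCAM-positive and CD11c-negative. Total RNA was extracted, and libraries were made with an Illumina TruSeq RNA kit and sequenced on an Illumina instrument, per the labels. Each population gave 1 library, from 14 pooled mice aged 7 days for cTEC and mTEC and from 7 pooled newborn mice for skinEC.

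The deposited workbook had 5 sheets. Its values were made by the authors as RPKM per gene, per the file headers. The submitters' processing notes name CASAVA 1.8.2 and the genome build mm9, without their role or order. The aligner, the gene annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, are uncertain. The gene models at hand belong to another build, so no coordinates are printed, and genes are named by the symbol and Entrez number the workbook pairs. The sorted RPKM values of 3 further sheets equalled those of the first (largest difference 0). A sheet also held log10 values deposited by the authors, which equalled log10 of RPKM plus 0.0001 and were not used further. The last sheet held identifiers without measurements.

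The first sheet had 22663 rows and 22609 symbols. For 47 symbols on more than 1 row, the row with the largest sum was kept. A spreadsheet had turned 11 symbols into dates, and these rows stay unnamed. Of the entries, 21080 were above 0 in at least 1 library, 16869 were at 1 RPKM or more in at least 1 library, and 1529 were at 0 in all 3, Ccl21a among them. An exact 0 can be a failed assignment of reads, so such a gene is only said to be listed at 0, and no fold against it is given. Small RNA entries (422 at 1 RPKM or more) can repeat the reads of their host gene. Mir5107, the second most abundant entry of both thymic libraries (4974 RPKM in cTEC, 12765 RPKM in mTEC), lies in this class.

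Read depth was estimated from the steps of low RPKM values, since the values of a gene in RPKM are whole multiples of what 1 read is worth. The steps of genes low in both libraries of a pair gave mapped read ratios of 1.02 for cTEC over mTEC (19 of 424 genes at a common ratio), 1.01 for cTEC over skinEC (94 of 851) and 0.993 for mTEC over skinEC (29 of 171). The absolute depth of mTEC came from 303 low genes drawn from the olfactory, type 1 vomeronasal, trace amine and bitter taste receptor families. Their coding lengths came from GENCODE M21, a later annotation. At the depth found, 79.2% of values were whole within a tolerance of 0.02 reads. This depth was about 55500000 reads, and the other depths followed from the ratios. The ratios were searched for only near 1, so a large difference in depth could not have been found by them alone. Over the low receptor genes with reads and a single coding length, values were whole for 320 of 411 in mTEC, 30 of 44 in cTEC and 5 of 11 in skinEC. The depths of cTEC and skinEC are therefore less certain. In mTEC, 46 receptor genes held 1 read, 102 held 2, 17 held 3 and 47 held 4, so reads were not taken as independent molecules and no counting interval was computed. On data simulated as whole reads, the search for the absolute depth was off by at most 0.002%. The ratios between libraries were not simulated. Summed RPKM was 462762 in cTEC, 474028 in mTEC and 595006 in skinEC.

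Ratios were computed as log2((RPKM + 1) / (RPKM + 1)), which understates the difference of low genes, over genes at 1 RPKM or more in at least 1 library. A gene was counted as higher or lower from a log2 ratio of 2 (4-fold). There is no p-value, since 1 library per population leaves no spread between replicates. Counts of genes were made per library at several RPKM levels. The overlap of the 2 comparisons that share skinEC is given beside n1 × n2 / N. The 48 gene lists (833 symbols, 824 of them in the table) were written before the data were examined. They cover thymic epithelial, antigen presentation, signalling, epidermal, junction, matrix and cell cycle genes, 10 lists of tissue-restricted genes, 11 lists of other cell types, RNA state, and the genes behind the sorting markers, which were not ranked. Some genes stand on several lists. For each of the 47 ranked lists the median log2 ratio of the members at 1 RPKM or more in at least 1 library was placed among 10000 random lists of the same size, drawn with a fixed seed within 20 bins of mean log2(RPKM + 1). The random range runs from percentile 2.5 to 97.5, and lists under 5 measured members would have had no percentile.

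Genes are named by a rule fixed in advance. Per comparison these are the 6 genes with the largest ratio in each direction among those at 10 RPKM or more in the higher library, leaving out provisional gene models and sorting genes; per list up to 4 members with the largest ratios and up to 2 that go against the median by 4-fold or, failing these, lie nearest to no difference; and a set of known thymic and epidermal genes. The ranking of lists and the count rule were tested on simulated data. With 200 genes changed 8-fold among 13887, 12032 and 13784 genes, 98.0%, 98.5% and 98.5% were recovered in cTEC over mTEC, cTEC over skinEC and mTEC over skinEC, with 0 unchanged genes called. That simulation drew independent reads, 50 per RPKM, for genes at a mean of 2 RPKM or more, without variation between animals or libraries. The 0 is therefore no measure of false calls in these libraries. Of 200 unshifted lists of 15 genes, 3.0%, 4.0% and 5.0% fell outside the range, and of lists shifted 8-fold 100% did. These lists were drawn at random from ratios permuted across genes, so small shares of unshifted lists were built in by the range. They are no measure of false calls for the real lists, whose genes can vary together.

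Alternatives were other pseudocounts, filters, fold thresholds and RPKM levels, 4 other scalings (TPM scale, TMM, upper quartile, and TPM without the 50 largest genes of each library), summed rows for repeated symbols, unmatched random lists and lists without their largest member. Leaving out small RNA entries and centring the ratios on the median gene were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.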

Results

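Messenger RNA was profiled by sequencing in 3 epithelial cell populations of C57BL/6 mice, with 1 library per population. Cortical thymic epithelial cells (cTEC), which line the outer thymus where immature thymocytes are selected, and medullary thymic epithelial cells (mTEC), which line the inner thymus where self-reactive thymocytes are removed, were sorted from the pooled thymi of 14 mice aged 7 days. Skin epithelial cells (skinEC), keratinocytes of the epidermis, were sorted from 7 pooled newborn mice and give an epithelium outside the thymus to compare with. Gene expression was read in RPKM (reads per kilobase of gene model, scaled by the mapped reads of the library). The reads behind the values were estimated at about 56600000 for cTEC, 55500000 for mTEC and 55900000 for skinEC, so that 3 reads on a gene of 1 kb correspond to 0.053, 0.054 and 0.054 RPKM. Since each population has 1 library, no difference has a replicate check, no test across samples was possible, and a gene was counted as higher or lower by a fixed rule of size, at least 4-fold on the log2(RPKM + 1) scale, over 16869 genes at 1 RPKM or more in at least 1 library. The median log2 ratio of a gene list is given with its random range, which holds the medians of size-matched and expression-matched random lists and describes these libraries only.

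The genes behind the sorting markers were read first, as a check of the labels. Epcam, the epithelial marker used in every sort, was at 223 RPKM in cTEC, 398 RPKM in mTEC and 142 RPKM in skinEC. Enpep, which encodes the Ly51 antigen used to take cTEC, was at 45.0 RPKM in cTEC, 11.6 RPKM in mTEC and 0.0553 RPKM in skinEC. The fucosyltransferase genes Fut1 and Fut2, whose products make the glycan bound by the lectin used to take mTEC, were at 38.4 and 35.1 RPKM in mTEC against 10.9 and 0.728 RPKM in cTEC and 5.72 and 1.89 RPKM in skinEC. Ptprc, which encodes the leukocyte antigen CD45 excluded from both thymic sorts, was at 1.07 RPKM in cTEC, 8.01 RPKM in mTEC and 0.0853 RPKM in skinEC. Itgax, which encodes CD11c, excluded from the skin sort, was at 0.180, 1.07 and 0.249 RPKM.

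The comparison of cTEC with mTEC asks how the epithelia of the thymic cortex and medulla differ. Genes of the cortical programme were far higher in cTEC. Prss16 (Entrez 54373), a thymus-specific serine protease, was at 4132 RPKM in cTEC and 25.2 RPKM in mTEC, a log2 ratio of 7.30, and Psmb11 (Entrez 73902), the catalytic subunit of the thymoproteasome, was at 261 against 1.66 RPKM. The chemokine gene Cxcl12 (404 against 3.78 RPKM) and the endocytic receptor gene Ly75 (220 against 9.19 RPKM) followed. Of the 17 genes in the cortical list, 11 were at least 4-fold higher in cTEC and 0 were lower, with a median log2 ratio of 2.76, above the random range of -0.15 to 0.65. The smallest ratios of the list were those of Bmp4 (0.49) and of the keratin gene Krt8 (1.17). The Notch ligand gene Dll4 was at 215 RPKM in cTEC and 19.4 RPKM in mTEC. In the same order, the thymocyte growth factor gene Il7 was at 103 and 24.4 RPKM and the chemokine gene Ccl25 at 1118 and 425 RPKM. Foxn1, the transcription factor gene needed for thymic epithelium to differentiate, was at 233 and 69.5 RPKM.

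The medullary programme lay on the other side. Aire (Entrez 11634), the transcriptional regulator that drives expression of tissue-restricted antigens, was at 1129 RPKM in mTEC and 1.20 RPKM in cTEC, the largest log2 ratio of the comparison by the naming rule (-9.01). Fezf2, a further regulator of such antigens, was at 231 against 0.353 RPKM, the costimulatory ligand gene Cd80 at 60.6 against 0.146 RPKM, and the transcription factor gene Spib at 204 against 3.97 RPKM. Of 19 measured medullary genes, 16 were at least 4-fold higher in mTEC, with a median log2 ratio of -3.92. Relb (-0.92) differed by under 4-fold, and so did Ltbr, a receptor gene of the TNF family, with its larger value in cTEC (131 against 37.2 RPKM). Ccl21a, a chemokine gene with near-identical copies, is listed at 0 in all 3 libraries, so its use in the medulla could not be read from these values. The thymus organogenesis transcription factors leaned to cTEC, with a median log2 ratio of 0.91, above the random range. Pax1 was at 514 RPKM in cTEC and 41.6 RPKM in mTEC and Hoxa3 at 15.5 and 1.90 RPKM, while Tbx3 was at 0.0874 and 6.84 RPKM.

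Outside these lists, the genes with the largest ratios toward cTEC included Gatsl3 (316 against 5.97 RPKM), Frmd6 (254 against 5.02 RPKM) and the synaptic vesicle gene Syngr1 (114 against 2.22 RPKM). Toward mTEC they were the milk casein gene Csn2 (Entrez 12991), at 1005 against 1.104 RPKM, the neuropeptide gene Calcb (332 against 0.0551 RPKM), the proteoglycan gene Srgn (1864 against 5.07 RPKM), the acute phase gene Saa3 (425 against 0.566 RPKM) and the calcium-binding protein gene S100a8 (300.4 against 0.135 RPKM).

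Lists of genes for presenting antigen to T cells lay toward mTEC. The invariant chain gene Cd74 was the most abundant gene of both thymic libraries, at 5669 RPKM in cTEC and 14483 RPKM in mTEC, and H2-Aa, a class II chain, was at 2257 and 5902 RPKM. Of 12 MHC class II presentation genes, 4 were at least 4-fold higher in mTEC, led by the protease gene Ctss (180 against 4.90 RPKM) and H2-Ob (29.98 against 0.662 RPKM), and the median log2 ratio was -1.45, below the random range of -0.19 to 0.73. Ciita, the master regulator of class II genes, differed little (83.4 RPKM in cTEC, 70.0 RPKM in mTEC). The MHC class I list had a median of -0.43, also below its random range, with 6 of 18 members at least 4-fold higher in mTEC. They included B2m, the class I light chain gene (5682 against 703 RPKM), its regulator Nlrc5 (28.6 against 2.26 RPKM) and H2-Q7 (241 against 13.6 RPKM), whose reads are uncertain because it has close copies. Proteasome subunits as a list lay within the random range (median 0.49), with Psmb11 higher in cTEC and Psme1 (38.6 RPKM in cTEC, 275 RPKM in mTEC) and Psmb8 (24.0 and 140 RPKM) higher in mTEC. The lysosomal proteases were divided. Prss16 and Ctsl, the cathepsin L gene (3967 against 211 RPKM), were higher in cTEC, and Ctsh (316 against 5.04 RPKM), Ctss and Napsa (43.0 against 0.669 RPKM) were higher in mTEC, with 6 of 15 members at least 4-fold higher in mTEC and a list median of -0.72. Against random lists not matched on expression, the class I and lysosomal medians came within the range, at percentiles 21.4 and 12.8. The 22 autophagy genes all stayed within 4-fold (median -0.03, percentile 2.95), from Map1lc3a (-1.35) to Wipi1 (1.20).

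Signals to thymocytes and leukocytes also differed. Of 23 chemokine genes, 18 were at least 4-fold higher in mTEC and 1, Cxcl12, was higher in cTEC. Cxcl9 was at 93.9 against 0.219 RPKM, Ccl20 at 95.2 against 0.993 RPKM and Ccl5 at 209 against 5.76 RPKM, and the list median was -3.32. Costimulation and checkpoint ligands had a median of -1.82, with 7 of 15 at least 4-fold higher in mTEC, among them Icosl (171 against 2.10 RPKM) and Cd86 (14.1 against 0.111 RPKM), and 2 higher in cTEC, Cd83 (218 against 13.8 RPKM) and Lgals9 (580 against 117 RPKM). The TNF receptor and non-canonical NF-kB list had a median of -1.10, with Tnfrsf11b, which encodes osteoprotegerin, at 75.7 against 0.433 RPKM and Tnfrsf11a, which encodes RANK, at 54.8 against 0.865 RPKM. Its percentile was 2.66 against unmatched random lists, just within the range. Thymocyte cytokines and growth factors (median -0.14), Notch pathway genes (-0.54), Wnt pathway genes (-0.56), interferon-stimulated genes (0.26) and antioxidant genes (0.16) lay within their random ranges as lists. Single members stood far apart, such as the Notch target gene Hey1 (114 RPKM in cTEC, 6.59 RPKM in mTEC), the ligand gene Wnt10a (0.234 and 27.6 RPKM), Wnt4 (152 and 17.9 RPKM), Bmp2 (0.618 and 20.9 RPKM), Kitl (44.4 and 5.69 RPKM), the interferon-stimulated Isg20 (260 and 38.8 RPKM), Gpx3 (6.11 and 278 RPKM) and Nqo1 (384 and 19.4 RPKM). Markers of myeloid and dendritic cells moved with the genes higher in mTEC. Of 15 such markers, 12 were at least 4-fold higher in mTEC (median -2.83, below the random range), with Lyz2 at 283 against 0.685 RPKM and Laptm5 at 460 against 2.41 RPKM.

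Genes of epithelial differentiation separated the thymic populations as well. Of 24 suprabasal and cornified envelope genes, 22 were at least 4-fold higher in mTEC, with a median of -3.63, such as Dmkn (143 against 0.782 RPKM) and Sprr1a (181 against 2.01 RPKM). Klk7 was at 50.4 RPKM in mTEC and is listed at 0 in cTEC. Claudins and tight junction genes had a median of -2.15, with Cldn7 at 171 against 2.56 RPKM and Cldn4 at 192 against 4.56 RPKM in mTEC, and Cldn8 on the other side (27.7 RPKM in cTEC, 1.74 RPKM in mTEC). Epidermal barrier lipid genes had a median of -1.17, below the random range. The basal keratinocyte list had a median of -0.14, at percentile 2.52 and so at the edge of the range, although its keratins Krt14 (17.7 against 229 RPKM) and Krt5 (45.8 against 475 RPKM) were higher in mTEC. Hair follicle genes (-1.29, percentile 3.17) and desmosome and adherens junction genes (-0.03) lay within the range, with Krt71 at 0.0163 against 24.1 RPKM and Dsg1a at 0.631 against 44.7 RPKM. The extracellular matrix and basement membrane list was higher in cTEC, with a median of 1.56, above the random range of -0.16 to 0.61, and 8 of 19 members at least 4-fold higher. Frem2 was at 52.4 against 1.57 RPKM, Lamc1 at 99.2 against 9.23 RPKM and Fn1, the fibronectin gene, at 278 against 46.5 RPKM, while Col7a1 was lower in cTEC (1.13 against 9.36 RPKM). The mitotic list (0.41) was within its range, with 28 of 28 members within 4-fold.

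Markers of tuft cells, a chemosensory epithelial cell type, showed the strongest median toward mTEC of the 47 ranked lists, at -4.80, with 10 of 11 members at least 4-fold higher. Gnat3, a taste G protein gene, was at 248 against 2.98 RPKM, Avil at 287 against 5.92 RPKM and Trpm5 at 159 against 3.44 RPKM. Among other cell types, Langerhans and skin T cell markers (-2.48) and fibroblast markers (-0.80) lay below the random range. The first came within it under 7 of 12 settings, such as a pseudocount of 0.1 RPKM (percentile 9.19), a filter at 5 RPKM (percentile 7.48) and leaving out the marker with the largest ratio (percentile 6.75). The second came within it under 2, no filter (percentile 3.61) and unmatched random lists (percentile 9.80). Thymocyte (-0.54), B cell (-1.82), erythroid (-1.17), endothelial (-0.04), pericyte and smooth muscle (-0.73), melanocyte and Schwann (-1.46) and Merkel cell markers (-1.58) lay within it. Cd4 was at 0.314 RPKM in cTEC and 8.13 RPKM in mTEC, Rag1 at 1.49 and 1.38 RPKM, and Col1a1 at 3.61 and 34.5 RPKM. As measures of RNA state, immediate early and heat shock genes (-0.06) and cytosolic ribosomal protein genes (0.54) were within the range.

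In all, 454 genes were at least 4-fold higher in cTEC and 2569 in mTEC, so that 15.02% of the genes apart were higher in cTEC. Of those higher in mTEC, 380 are listed at 0 in cTEC, and 1 of those higher in cTEC is listed at 0 in mTEC. A further 58.3% of the genes were within 2-fold. Of the 47 ranked lists, 3 lay above the random range, 23 below and 21 within it. Of the 21, 9 came outside under at least 1 alternative setting. Against unmatched random lists, ribosomal protein genes (percentile 99.78), mitotic genes (percentile 98.83) and proteasome subunits (percentile 98.5) lay above the range, and testis genes, B cell markers (percentile 1.14) and hair follicle genes (percentile 1.39) below it. The Notch and basal keratinocyte lists crossed its lower edge with a pseudocount of 0.1 RPKM (percentiles 2.40 and 2.27), and endothelial markers its upper edge without their largest member (percentile 98.69). The count higher in mTEC was 4554 with a pseudocount of 0.1 RPKM, since low genes then pass the rule more easily.

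**Figure D1:**
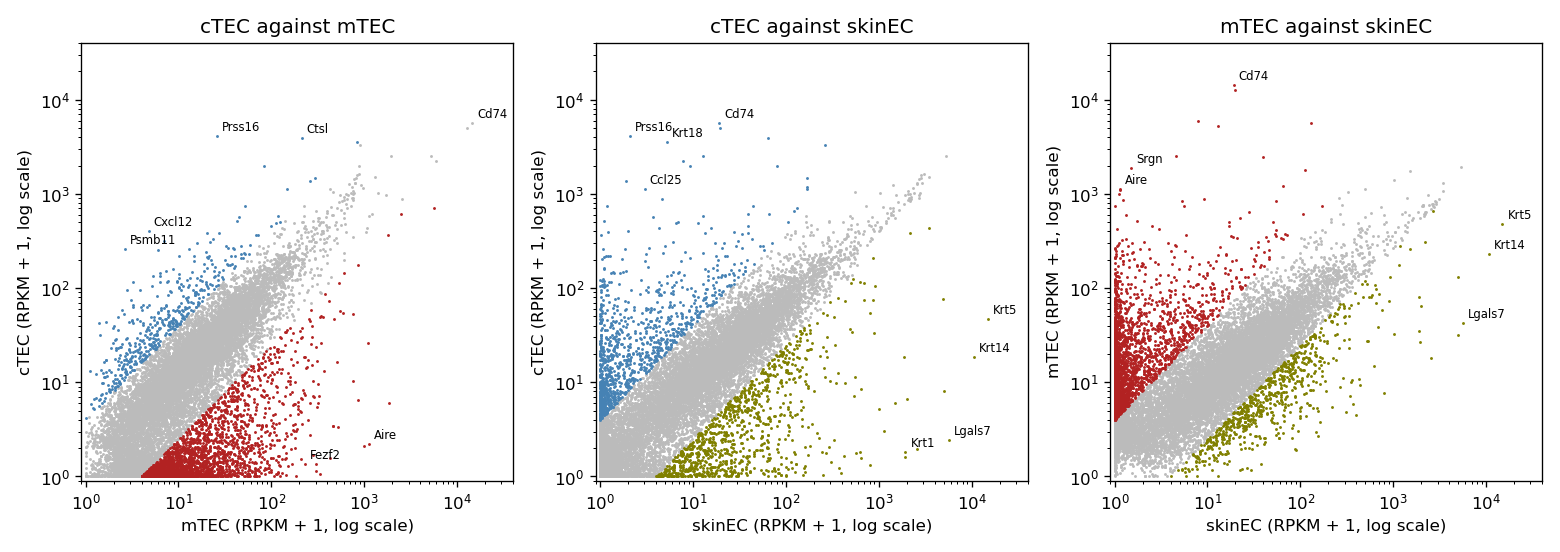
Expression of 16869 genes in pairs of libraries, both axes in RPKM + 1 on a log scale, 1 point per gene. Coloured points are at least 4-fold apart on that scale, in the colour of the library in which they are higher (cTEC blue, mTEC red, skinEC olive), and grey points are within 4-fold. The field below the grey band in the first panel holds 2569 genes and the field above it 454.

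The breadth of expression was compared because mTEC are known for transcribing genes of many other tissues. At 1 RPKM or more there were 16375 genes in mTEC, against 12595 in cTEC and 12092 in skinEC, and 3326 genes reached this level in mTEC alone, against 206 in cTEC alone and 180 in skinEC alone. The gap narrowed above 1 RPKM. At 10 RPKM or more the libraries held 8251, 7743 and 7662 genes, and at 100 RPKM or more mTEC held the fewest, 696 against 772 in cTEC and 996 in skinEC. The 10 most abundant genes took 11.5% of the summed RPKM in mTEC, 7.54% in cTEC and 10.01% in skinEC.

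Genes restricted to other tissues were part of this breadth. Of 181 genes in 10 lists of tissue-restricted genes, 148 were at 1 RPKM or more in mTEC, 31 in cTEC and 17 in skinEC, and 70, 7 and 4 reached 10 RPKM. At 0.1 RPKM or more they numbered 176, 82 and 46, a narrower gap. The count in cTEC was 50 at level 1 of the TPM scale and 54 on that scale without the 50 largest genes of each library. In mTEC 1 of the 181 is listed at 0, in cTEC 60 and in skinEC 95. Liver genes at 1 RPKM or more numbered 18 of 20 in mTEC and 1 in cTEC, with the apolipoprotein gene Apoa1 at 65.6 against 0.215 RPKM and the albumin gene Alb at 17.8 RPKM in mTEC and listed at 0 in cTEC. Pancreas genes numbered 17 of 20 against 2, with Iapp, the islet amyloid gene, at 124 against 0.280 RPKM and the somatostatin gene Sst at 65.3 against 0.0590 RPKM. The insulin gene Ins2 was at 17.7 RPKM in mTEC and is listed at 0 in cTEC and skinEC. Gut genes numbered 19 of 21 against 4, with the transcription factor gene Cdx1 at 149 against 0.283 RPKM and the antimicrobial lectin gene Reg3g at 1091 against 25.02 RPKM, and Tff1 as an exception (3.28 against 8.43 RPKM). Mammary, salivary and lacrimal genes numbered 14 of 16 against 5, with the kallikrein gene Klk1 at 77.6 against 0.605 RPKM, while Bpifa1 was abundant in both (207 RPKM in mTEC, 363 RPKM in cTEC). Amy1, which shares reads with close copies, was at 2.83 against 2.28 RPKM.

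Lung genes numbered 14 of 14 in mTEC and 5 in cTEC, led by Scgb1a1, the club cell secretoglobin gene (93.6 against 0.113 RPKM). Skeletal muscle genes numbered 17 of 18 against 3, with the myogenic factor gene Myog at 56.4 against 0.0716 RPKM and Actn3 high in both (199 and 145 RPKM). Brain genes numbered 15 of 19 against 5, with Syt1 at 87.8 against 0.473 RPKM and the neurofilament gene Nefm higher in cTEC (6.79 against 35.3 RPKM). Thyroid, pituitary and adrenal genes numbered 15 of 19 against 3, with the calcitonin gene Calca at 117 against 0.434 RPKM and Pomc at 89.0 against 0.404 RPKM. Eye genes numbered 9 of 16 against 2, with the lens crystallin gene Cryaa at 23.1 RPKM in mTEC and listed at 0 in cTEC. Testis genes were the weakest of these lists. They numbered 10 of 18 against 1, and 0 of them reached 10 RPKM in mTEC, with the protamine gene Prm1 at 4.24 against 0.133 RPKM.

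As list medians of cTEC over mTEC, 9 of the 10 tissue lists lay below the random range, at -3.50 for liver, -3.66 for pancreas, -3.79 for gut, -3.76 for mammary, salivary and lacrimal, -2.21 for skeletal muscle, -2.46 for brain, -2.21 for eye, -2.58 for lung and -1.99 for thyroid, pituitary and adrenal genes. The testis list (-1.47, percentile 19.4) lay within it, and below it against unmatched random lists (percentile 1.97). The brain and eye lists came within the range under 1 or more alternative settings, brain with a filter at 5 RPKM (percentile 3.84) and eye with no filter (percentile 3.55). Every measured member of the 10 lists was at 1 RPKM or more in mTEC, so the filter itself favoured medians toward mTEC. With no filter, eye was the only one of the 9 lists to come within the range.

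**Figure D2:**
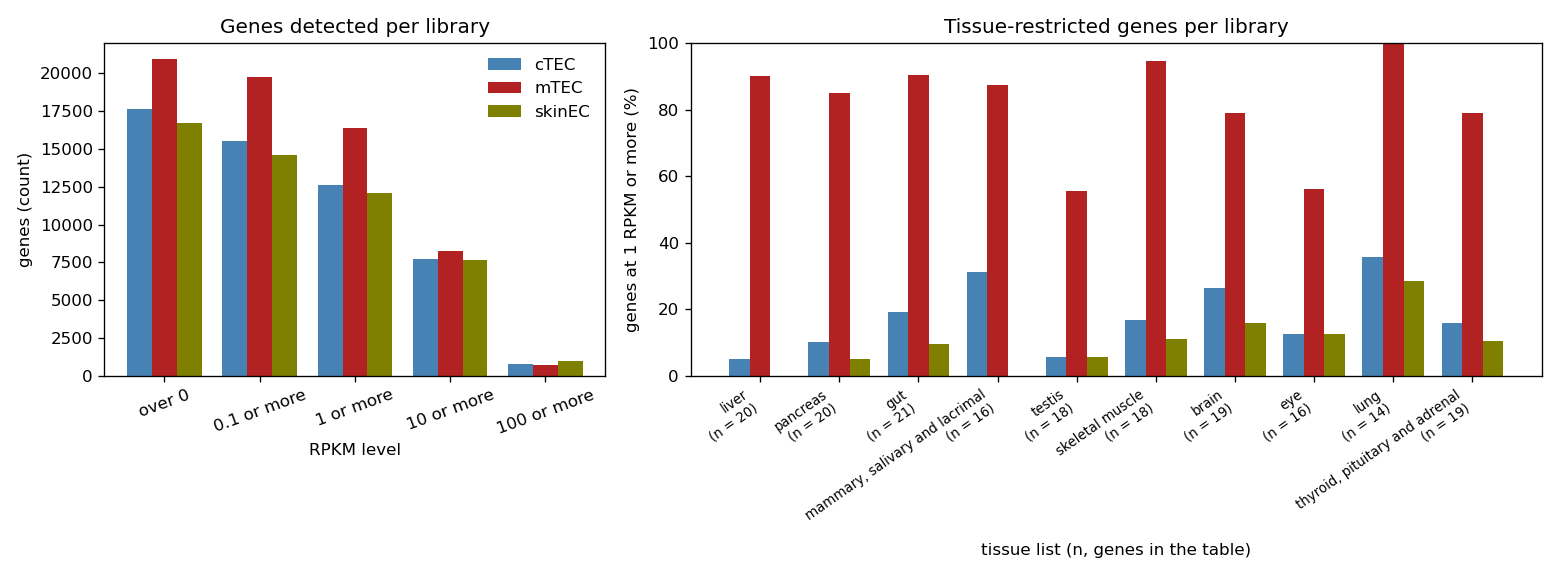
Left, number of genes per library over 0 RPKM and at 0.1, 1, 10 and 100 RPKM or more. Right, percent of the genes of each of 10 tissue-restricted lists at 1 RPKM or more, with n the number of list genes in the table. Each bar is 1 library (cTEC blue, mTEC red, skinEC olive), so there are no error bars. mTEC holds 16375 genes at 1 RPKM or more against 12595 and 12092, and has the tallest bar in every tissue list.

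The comparison of cTEC with skinEC sets the cortical epithelium against that of the epidermis. The largest ratios toward cTEC were those of thymic and simple epithelial genes. Prss16 was at 4132 against 1.11 RPKM, Crip3 at 1379 against 0.891 RPKM, the simple epithelial keratin gene Krt18 at 3549 against 4.30 RPKM, Tbata at 743 against 0.190 RPKM, Pax1 at 514 against 0.109 RPKM and Ccl25 at 1118 against 2.01 RPKM. Toward skinEC they were the keratinocyte genes Lgals7 (5661 against 1.45 RPKM), Krt79 (1900 against 0.590 RPKM), Krt1 (1940 against 0.838 RPKM), Krt15 (4983 against 7.02 RPKM) and Krt14 (10673 against 17.7 RPKM), and the stefin gene Stfa3 (2555 against 0.943 RPKM), whose reads are uncertain because of close copies. Krt5, the most abundant gene of skinEC, was at 15010 RPKM there and 45.8 RPKM in cTEC.

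The cortical list had a median log2 ratio of 7.49, with 15 of 17 members at least 4-fold higher in cTEC. Dll4 was at 215 against 0.104 RPKM, Il7 at 103 against 0.0434 RPKM, Psmb11 at 261 against 0.0632 RPKM and Krt8 at 1990 against 8.25 RPKM. The organogenesis factors had a median of 2.99, with Foxn1 at 233 against 3.75 RPKM, while Lhx2 (0.0696 against 57.3 RPKM) and Tbx1 (0.805 against 28.2 RPKM) were higher in skinEC. MHC class II genes had a median of 6.00 with 9 of 12 at least 4-fold higher, such as Cd74 (5669 against 18.1 RPKM) and H2-Aa (2257 against 6.90 RPKM), and MHC class I genes a median of 2.08 with 10 of 18, such as Psmb9 (435 against 3.33 RPKM) and H2-K1 (610 against 38.2 RPKM). Interferon-stimulated genes were higher nearly throughout, with 20 of 21 at least 4-fold higher in cTEC and a median of 3.08. Isg20 was at 260 against 0.852 RPKM and Oasl2 at 193 against 2.01 RPKM, and the exception Oas2 was at 2.10 against 0.116 RPKM.

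The medullary list (median 0.94), lysosomal proteases (0.56), costimulation and checkpoint ligands (0.72), TNF receptor and non-canonical NF-kB genes (0.88), antioxidant genes (0.26) and extracellular matrix genes (0.47) also lay above their random ranges. Members of opposite direction stood in several of them. Ctsl was at 3967 against 63.4 RPKM and Ctsh at 5.04 against 43.9 RPKM, and Nid2 at 62.6 against 1.32 RPKM and Col7a1 at 1.13 against 183 RPKM. The antioxidant list came within the range against unmatched random lists (percentile 95.2). Chemokines (0.29), thymocyte cytokines (0.20), the Notch list (0.21), proteasome subunits (-0.13), autophagy genes (-0.12) and tight junction genes (0.03) lay within their ranges as lists, although Cxcl12 (404 against 1.00 RPKM), Cxcl14 (0.639 against 426 RPKM), Flt3l (70.7 against 3.06 RPKM), Lfng (1.02 against 63.5 RPKM) and Cldn1 (3.89 against 111 RPKM) stood far apart.

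Epidermal programmes were lower in cTEC. The suprabasal list had a median of -3.71, with 18 of 24 members at least 4-fold higher in skinEC, among them Krt10 (1998 against 5.65 RPKM) and Krtdap (1150 against 2.01 RPKM). Basal keratinocyte genes had a median of -1.84, with the hemidesmosome gene Col17a1 at 1011 against 4.25 RPKM and the integrin gene Itgb1 near no difference (107 against 94.9 RPKM). Hair follicle genes (-2.21), desmosome and adherens junction genes (-1.29), barrier lipid genes (-0.77) and Wnt pathway genes (-0.95) also lay below their ranges. Gata3 was at 87.7 against 0.605 RPKM, Pkp1 at 644 against 7.39 RPKM and Wnt10a at 73.7 against 0.234 RPKM, while Dsc2 was higher in cTEC (147 against 5.03 RPKM). Mitotic genes had a median of -2.26, with 18 of 28 at least 4-fold higher in skinEC and 0 in cTEC, such as Ube2c (137 against 12.2 RPKM) and Top2a (159 against 17.2 RPKM). Cytosolic ribosomal protein genes (-1.16) and immediate early and heat shock genes (-1.46) were below the range as well, with Egr2 at 123 against 0.113 RPKM and Atf3 at 189 against 2.61 RPKM.

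Of the tissue-restricted lists, gut genes lay just above the range (0.19, percentile 97.7), a position lost with a pseudocount of 0.1 RPKM (percentile 97.05) and under 5 other settings, and the other 9 lay within it, with medians from 0.00 to 0.21. Endothelial (1.57), pericyte and smooth muscle (1.39) and fibroblast markers (1.17) lay above their ranges, with Pecam1 at 6.34 against 0.224 RPKM, Myh11 at 102 against 0.111 RPKM and Dpt at 25.3 RPKM in cTEC and listed at 0 in skinEC. The endothelial list came within the range with a filter at 5 RPKM (percentile 93.7). Thymocyte (0.44), myeloid and dendritic (0.19), Langerhans and skin T cell (0.42), B cell (0.08), erythroid (0.06), melanocyte and Schwann (0.21), Merkel cell (0.00) and tuft cell markers (0.63) lay within theirs. Of the lists within, 4 came above the range under at least 1 setting, chemokines with a pseudocount of 0.1 RPKM (percentile 99.86), mammary, salivary and lacrimal genes under 3 settings (percentile 98.83 with a filter at 5 RPKM), and thymocyte and tuft cell markers against unmatched random lists (percentiles 97.62 and 97.96).

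In all, 1062 genes were at least 4-fold higher in cTEC and 981 in skinEC, so that 52.0% of the genes apart were higher in cTEC. On the TPM scale, which changes both the scaling between the libraries and the size of the pseudocount in RPKM terms, 1642 genes were higher in cTEC and the share was 63.1%. With a pseudocount of 0.5 RPKM and the scaling kept, the share was 53.5%. Age and organ differ together between these libraries, 7 days against newborn, and so do the gates, since CD45 was not part of the skin sort.

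The comparison of mTEC with skinEC sets the medullary epithelium against the epidermis. Toward mTEC the largest ratios were those of Srgn (1864 against 0.515 RPKM), Aire (1129 against 0.148 RPKM), Reg3g (1091 against 0.139 RPKM), Csn2 (1005 against 0.112 RPKM) and Cd74 (14483 against 18.1 RPKM), with the fatty acid binding protein gene Fabp4 at 747 RPKM in mTEC and listed at 0 in skinEC. Toward skinEC they were Krt15 (4983 against 30.5 RPKM), Stfa3 (2555 against 17.2 RPKM), Lgals7 (5661 against 41.5 RPKM), Stfa1 (392 against 3.45 RPKM), Krt1 (1940 against 25.6 RPKM) and the BMP antagonist gene Sostdc1 (306 against 3.82 RPKM).

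The medullary list had a median log2 ratio of 5.60, with 14 of 19 members at least 4-fold higher in mTEC, such as Fezf2 (231 against 0.0388 RPKM), Spib (204 against 0.604 RPKM) and Cd80 (60.6 against 0.284 RPKM). The keratins Krt14 (229 against 10673 RPKM) and Krt5 (475 against 15010 RPKM) went the other way. The cortical list (3.63) and the organogenesis factors (2.27) were above their ranges too, with Krt8 at 886 against 8.25 RPKM, Foxn1 at 69.5 against 3.75 RPKM and Trp63 lower in mTEC (27.1 against 292 RPKM). All 12 MHC class II genes were at least 4-fold higher in mTEC (median 7.23), with H2-Aa at 5902 against 6.90 RPKM and H2-DMb2 at 600 against 0.319 RPKM, and 13 of 18 class I genes (2.95), with B2m at 5682 against 129 RPKM. In the same comparison 12 of 15 myeloid and dendritic markers were at least 4-fold higher in mTEC. Interferon-stimulated genes had a median of 3.59 with 18 of 21 at least 4-fold higher, such as Usp18 (123 against 1.799 RPKM) and Irf7 (119 against 3.53 RPKM).

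Chemokines (4.21), costimulation and checkpoint ligands (3.75), lysosomal proteases (1.72), TNF receptor and non-canonical NF-kB genes (1.68), tight junction genes (1.91) and thymocyte cytokines (1.29) were above their ranges. Ccl22 was at 55.9 against 0.148 RPKM, Cd40 at 134 against 0.0963 RPKM, Icosl at 171 against 0.945 RPKM, Cldn3 at 110 against 0.397 RPKM and Ctss at 180 against 1.03 RPKM, and Ccl5 was at 209 RPKM in mTEC and is listed at 0 in skinEC. Cxcl14 (9.89 against 426 RPKM) and Cldn1 (20.7 against 111 RPKM) were lower in mTEC. The cytokine list came within the range under 3 settings, among them a filter at 5 RPKM (percentile 94.4). Antioxidant genes lay above it at a median of 0.13 (percentile 98.9), which came within the range against unmatched random lists (percentile 46.5) and turned to -0.04 when the ratios were centred on the median gene, with Gpx3 at 278 against 0.409 RPKM. Tuft cell markers had a median of 5.54, with Gnat3 at 248 against 0.0305 RPKM and Trpm5 at 159 against 0.0204 RPKM, while Pou2f3, a transcription factor gene of tuft cells and keratinocytes, had its larger value in skinEC, by under 4-fold (64.7 against 182 RPKM).

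Suprabasal genes were divided between the libraries. Their median was 0.20, within the random range, with 5 members at least 4-fold higher in mTEC and 4 in skinEC of 24. Rptn, the repetin gene, was at 98.4 against 0.462 RPKM, Krt10 at 63.4 against 1998 RPKM, and Lor, the loricrin gene, at 38.0 against 30.3 RPKM. Barrier lipid genes (0.06), the Notch list (-0.27), proteasome subunits (-0.42) and autophagy genes (-0.20) were within the range, the Notch list below it with a filter at 5 RPKM (percentile 0.06). Basal keratinocyte genes (-2.29), hair follicle genes (-1.46), desmosome and adherens junction genes (-1.26), Wnt pathway genes (-1.40) and extracellular matrix genes (-0.96) were below theirs, with Col17a1 at 31.8 against 1011 RPKM, Lhx2 at 1.58 against 57.3 RPKM, Dsc3 at 9.06 against 348 RPKM, Wnt16 at 0.227 against 25.5 RPKM and Frem2 at 1.57 against 58.0 RPKM. The matrix list came within the range without its largest member (percentile 3.38). Mitotic genes had a median of -2.71, with 23 of 28 at least 4-fold higher in skinEC, such as Mcm5 (139 against 11.5 RPKM). Ribosomal protein genes (-1.64) and immediate early and heat shock genes (-1.43) were also below their ranges, with Rpl8 at 665 against 2683 RPKM and Jun at 80.3 against 580 RPKM.

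Of the tissue-restricted lists, 9 lay above the random range, with medians of 3.72 for liver, 4.22 for pancreas, 3.79 for gut, 4.75 for mammary, salivary and lacrimal, 2.70 for skeletal muscle, 2.52 for brain, 2.21 for eye, 2.24 for lung and 3.47 for thyroid, pituitary and adrenal genes, and the testis list was within it (1.81, percentile 95.7), and above it against unmatched random lists (percentile 99.07). The brain and eye lists came within it without their largest member (percentiles 95.9 and 93.1), brain under 3 settings in all. Here too every measured member was at 1 RPKM or more in mTEC, so the filter favoured medians toward mTEC. With no filter, the 9 lists stayed above the range. Myeloid and dendritic (3.05), pericyte and smooth muscle (3.58), fibroblast (2.59), erythroid (2.22) and Merkel cell markers (2.78) lay above their ranges, with Lyz2 at 283 against 0.0847 RPKM, Rgs5 at 114 against 0.00990 RPKM, Col1a1 at 34.5 against 1.07 RPKM, Alas2 at 8.67 against 0.293 RPKM and Krt20 at 42.3 against 5.30 RPKM. The myeloid and Merkel cell lists came within the range with a filter at 5 RPKM (percentiles 95.8 and 93.1), and the latter also with a pseudocount of 0.1 RPKM (percentile 90.2). Thymocyte (1.13), Langerhans and skin T cell (2.40), B cell (1.88), endothelial (1.78) and melanocyte and Schwann markers (1.39) were within theirs. Endothelial markers came above the range under 4 settings (percentile 99.54 against unmatched random lists), and Langerhans and skin T cell and B cell markers under 2 (percentiles 99.68 and 98.35 against unmatched lists).

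In all, 2834 genes were at least 4-fold higher in mTEC and 708 in skinEC, so that 80.0% of the genes apart were higher in mTEC, and 749 of the 2834 are listed at 0 in skinEC. The TPM scale gave 4321 genes higher in mTEC. The median log2 ratio of all genes was 0.16 in RPKM and 0.47 on that scale, and the same limits of age, organ and gate apply as for cTEC.

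**Figure D3:**
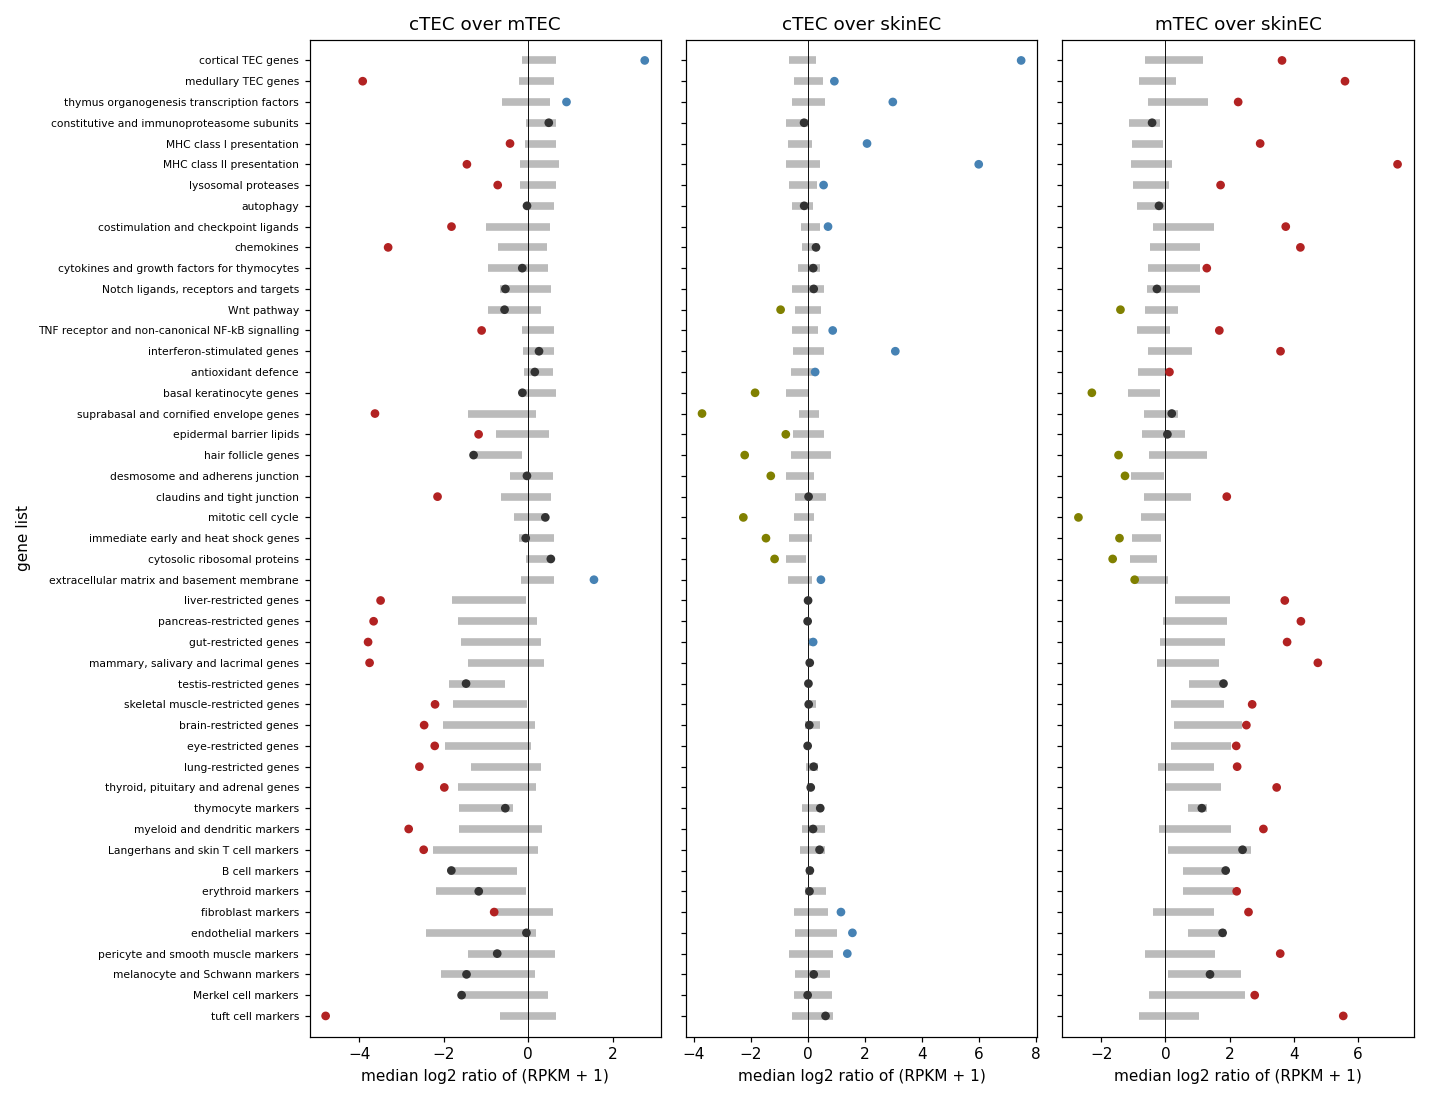
Median log2 ratio of (RPKM + 1) of 47 gene lists in each comparison (points), with the random range as grey bars. Points outside the bar carry the colour of the library in which the list is higher (cTEC blue, mTEC red, skinEC olive) and points inside it are black. In cTEC over mTEC, 3 lists lie above and 23 below their bars, in cTEC over skinEC 15 and 9, and in mTEC over skinEC 28 and 8.

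Genes that set both thymic populations apart from the skin were counted together. There were 551 genes at least 4-fold higher in both cTEC and mTEC than in skinEC, where independent lists of these sizes would share 178, and 431 genes lower in both, where independent lists would share 41.2. The count higher in both depends on the scale. It was 830 with a pseudocount of 0.5 RPKM and 1512 with 0.1 RPKM, where independent lists would share 319 and 593, and 997 on the TPM scale, where they would share 421. A further 25 genes were at least 4-fold apart from skinEC in opposite directions. Both ratios share the skin library, which cannot be split, so the 2 comparisons are not independent of each other. The cortical, medullary, organogenesis, class I, class II, lysosomal protease, costimulation, TNF receptor, interferon-stimulated and antioxidant lists were above the random range in both comparisons, and so were gut-restricted genes and the markers of fibroblasts and of pericytes and smooth muscle. The mitotic, basal keratinocyte, Wnt, hair follicle, desmosome and adherens junction, ribosomal, and immediate early and heat shock lists were below it in both. The antioxidant and gut lists did not keep this position under every setting.

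Across the 16869 genes, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.705 between cTEC and mTEC, 0.800 between cTEC and skinEC and 0.657 between mTEC and skinEC. Spearman's rho was 0.703, 0.809 and 0.654. By this measure cTEC lay nearer to skinEC than to mTEC, an order that r kept under all 10 alternative settings run for it. The gene set holds 3326 genes at 1 RPKM or more in mTEC alone, against 206 in cTEC alone and 180 in skinEC alone. Such genes can lower r for both pairs with mTEC, and no setting left them out as a class.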

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

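Of 182 recomputed counts and correlations, 136 stayed within 1.5 times their value (or within a small fixed margin, for r) and 46 moved. A count could not be labelled reversed, only an r that changed sign, so the 0 reversals carry no weight. No paired analysis was possible because each population has 1 library, and leaving out a library would leave no comparison. The other sheets held the same values, so they gave no separate result. Leaving out small RNA entries and centring on the median gene were chosen after seeing the data. Of 86 list medians outside the random range, 69 stayed outside under all 12 list settings, 17 came within it under at least 1, and 1 changed sign, antioxidant genes in mTEC over skinEC, at -0.0361 when centred on the median gene. Centring could not move a percentile, since it shifts the list and the random lists alike. Summing repeated rows left the counts of genes apart unchanged, so these 2 settings add little to the 69. Of 55 list medians within the range, 18 came outside under at least 1 setting, 12 of them against unmatched random lists. Of 942 ratios of list members and top genes at 4-fold or more, over all comparisons, 0 changed sign and 0 fell under 2-fold in 10 settings. That outcome was largely fixed in advance. Smaller pseudocounts enlarge a ratio, and the scalings shifted the median ratio by far less than 4-fold.

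A pseudocount of 0.1 RPKM lets lower genes pass. It gave 4554 genes lower in cTEC than mTEC, 1989 higher and 1490 lower in cTEC than skinEC, 5030 higher in mTEC than skinEC, 1512 higher in both, and an r of 0.605 between mTEC and skinEC. With 0.5 RPKM, 830 were higher in both. The TPM scale makes the pseudocount smaller in RPKM terms and also rescales the libraries against each other. The share higher in cTEC than skinEC was 63.1% on it, against 53.5% with a pseudocount of 0.5 RPKM alone. It gave 1642 genes higher in cTEC and 4321 in mTEC than in skinEC, 997 higher in both, and 50 tissue-restricted genes at its level 1 in cTEC. Without the 50 largest genes of each library it gave 3984 genes lower in cTEC than mTEC, 1668 and 4683 higher in cTEC and mTEC than skinEC, 1067 higher in both, and 54 tissue-restricted genes in cTEC. The TPM scale moved the median log2 ratio of all genes to 0.20 in cTEC over skinEC and 0.47 in mTEC over skinEC, from 0.00 and 0.16, and upper quartile scaling moved the latter to 0.35.

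By construction the thresholds moved the counts. At 2-fold, 1834 genes were higher and 5203 lower in cTEC than mTEC, 2596 and 2418 in cTEC than skinEC, 5736 and 2812 in mTEC than skinEC, and 1588 and 1434 in both. At 8-fold the counts were 122 and 1204, 507 and 447, 1464 and 194, and 239 and 127. At 0.1 RPKM, 82 tissue-restricted genes were reached in cTEC, 176 in mTEC and 46 in skinEC. At 10 RPKM the libraries held 7743, 8251 and 7662 genes and 7, 70 and 4 tissue-restricted genes (cTEC, mTEC, skinEC). Without a filter r was 0.793, 0.850 and 0.754, and with a filter at 5 RPKM 0.560, 0.708 and 0.489 (cTEC and mTEC, cTEC and skinEC, mTEC and skinEC), since a filter changes which low genes enter. Estimated depth was alike in all libraries, less surely for cTEC and skinEC, but only depth ratios near 1 were searched. It sets a floor near 0.054 RPKM for 3 reads on 1 kb.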

Other observations

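Several gene families not on the lists were read after their values had been seen. Bitter taste receptor genes were at 1 RPKM or more for 24 of 35 members in mTEC and for 0 in cTEC and skinEC, led by Tas2r108 (18.8 RPKM in mTEC, 0.158 RPKM in cTEC) and Tas2r105 (13.9 RPKM in mTEC, listed at 0 in the others). The Skint genes, a family known from the thymic selection of epidermal gamma-delta T cells, had a mean of 61.8 RPKM in mTEC, 0.779 RPKM in cTEC and 3.28 RPKM in skinEC over 11 genes. Skint10 was at 192 RPKM in mTEC, 3.59 RPKM in cTEC and 0.217 RPKM in skinEC, and Skint1 at 160 RPKM in mTEC, 1.85 RPKM in cTEC and 21.7 RPKM in skinEC. Of 27 prolactin family genes, 27 were above 0 in mTEC, 0 in cTEC and 1 in skinEC, at a mean of 0.771 RPKM in mTEC. Members of these families are alike in sequence, so the values of single members are uncertain.

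Families used mainly in sensory neurons were reached more often in mTEC than in the other libraries, at low level. Of 1125 olfactory receptor genes, 483 were above 0 in mTEC, 45 in cTEC and 11 in skinEC, and 11 were at 1 RPKM or more in mTEC, with Olfr461 at 13.5 RPKM. Of 208 type 1 vomeronasal receptor genes, 61 were above 0 in mTEC and 0 reached 1 RPKM. Mucin genes had a mean of 12.4 RPKM in mTEC and 0.434 RPKM in cTEC. Beta defensin genes had a mean of 4.49 RPKM in mTEC, 0.0323 RPKM in cTEC and 1.63 RPKM in skinEC over 43 genes, carried by few members, since the median in mTEC was 0.684 RPKM. Defb6 was at 83.7, 0.219 and 24.9 RPKM, and Defb1 was highest in skinEC (9.39, 0.637 and 44.8 RPKM in mTEC, cTEC and skinEC). Keratin-associated protein genes were an exception by mean only, at 0.320 RPKM in mTEC, 0.330 RPKM in skinEC and 0.00712 RPKM in cTEC over 51 genes. By count, 38 were above 0 in mTEC, 30 in skinEC and 4 in cTEC, and 5, 1 and 0 reached 1 RPKM. On the cortical side, the parathyroid hormone gene Pth was at 103 RPKM in cTEC and 28.1 RPKM in mTEC and is listed at 0 in skinEC, while the parathyroid transcription factor gene Gcm2 was at 0.497 and 1.14 RPKM and the calcium-sensing receptor gene Casr at 1.94 and 15.4 RPKM in cTEC and mTEC.

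Of the explanations weighed below, the tests of depth, of blood cells and of myeloid cells were chosen after the result was seen. More genes were at 1 RPKM or more in mTEC (16375) than in cTEC (12595). A deeper mTEC library is argued against by the estimated reads, whose ratio of mTEC to cTEC was 0.98. The search covered only ratios near 1. At the cTEC depth it gave, 30 of 44 low receptor genes in cTEC held whole reads, and 7 held a single read. Had cTEC held several times fewer reads, single reads at that depth would be rare. An even low background of reads is argued against only for a background of the size read in vomeronasal receptor genes. Subtracting 0.132 RPKM, the 95th percentile of 328 such genes in mTEC, from every gene left 16058 genes at 1 RPKM or more. A subtraction this small can only move genes just above 1 RPKM. The median of both types of these receptor genes in mTEC was 0, so a background that they miss was not tested. Blood cells as the whole cause are argued against by 54 of 61 liver, pancreas and gut genes at 1 RPKM or more in mTEC, against 7 in cTEC and 3 in skinEC. Admixed cells as part of the cause were not excluded, and the depth estimate rests on low genes. Transcription of tissue-restricted genes by mTEC is a candidate explanation. It stays a hypothesis, since it was found and tested on the same libraries. Replicate libraries or libraries of single mTEC, not used here, would be needed to decide it.

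Myeloid and dendritic markers were higher in mTEC than in cTEC, although CD45-positive cells were gated out of both sorts. Such cells in the mTEC sort cannot be told apart from transcription by mTEC, since the design holds 0 libraries of myeloid or dendritic cells to compare with. Genes for class II presentation, chemokines and costimulation are used by such cells too, so their part in these lists stays open for mTEC over skinEC as well, where 12 of 15 markers were at least 4-fold higher in mTEC. It stays open too for single genes with large ratios toward mTEC, such as Srgn and S100a8. Laptm5 was at 460 RPKM and Lyz2 at 283 RPKM in mTEC, Ptprc at 8.01 and Tyrobp at 7.13 RPKM. Of the 15 markers, 5 were at 1 RPKM or more in cTEC too, and 4 also stand on the list of Langerhans and skin T cell markers.

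Mitotic genes were lower in both thymic libraries than in skinEC. The scaling of the libraries is argued against by the list's median log2 ratio, which was at most -1.95 under 4 other scalings in either comparison. The age difference between the thymus and skin donors cannot be told apart from the organ, since the design holds 0 skin libraries of the same age as the thymus libraries. A difference of organ or cell type stays open as the biological explanation and was not tested.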
